A study of Homo sapiens with 12 samples.

How the data were processed

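SMC1A HiChIP libraries were made from Kelly cells in 4 groups of 3 libraries: sensitive, resistant, resistant shBORIS and resistant shGFP. Resistant cells were kept in 1 µM TAE684 and hairpin cells were infected for 24 h with 8 µg/ml polybrene and selected for 48 h, per the labels' protocols. The labels do not say whether the 3 libraries of a group came from separate cultures.

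The submitters' processing notes name Trimmomatic, HiC-Pro and the build hg19 (GRCh37), without versions. How replicates were combined and which program computed the fold changes are not given in the sources used here. The authors deposited, for each of the 2 comparisons, a table of loops with 2 columns of whole-number tag counts, 1 per group, that sum to the total in 100% of the loops. The log2 fold change of each loop is the authors' own, per the file headers, and sets the first group over the second. It does not follow from the pooled tags alone: 1910 calls in resistant against sensitive cells and 1889 in shBORIS against shGFP did not reach 2-fold in the called direction by the pooled ratio, among them 2 and 15 of the opposite sign. All calls and class medians in the report rest on this column unless the pooled ratio is named. The p-value and FDR that the authors deposited for each loop carry the name of the loop caller mango in the header, and judge the loop against background, not a difference between groups. Every FDR was under 0.01, with highest values of 0.00993 and 0.00999. The deposited loop width, a value in base pairs, is the distance between anchor midpoints. The authors' loop classes name each anchor as a CTCF site, an enhancer or a promoter. The authors' calls of gained and lost equalled a log2 fold change of at least 1 in either direction in 100% of loops, with no p-value of the difference. Display copies of both tables were not used here.

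Anchor positions are printed as 1-based, with 1 added to the deposited starts, which count from 0. The highest anchor end on chromosome 1, 249225703, shows that positions are not those of GRCh38, the build of the gene annotation at hand, so loops are reported by position and class, and the gene lists fixed before the data were examined were not run. The rule for named features, also fixed then, became the 10 gained and 10 lost loops of largest authors' fold change per comparison.

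The planned edgeR quasi-likelihood tests, Fisher tests, length permutation tests and gene list tests need counts per library or genes per loop, so they were not run. In their place, the authors' calls are described as theirs, and class medians and length differences were ranked among 10000 random relabellings of loops within 10 depth classes, or within 5 strata each of tag total and length. These percentiles describe the pooled libraries, and loops are not independent replicates.

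The authors' scaling was read from 706 and 543 loops of at least 1000 tags as the difference between the log2 ratio of the group columns and their fold change. All of these loops lay inside the chromosome 2 segment, since loops outside it had at most 536 and 215 tags. The scaling was 0.337 (SD 0.0045 over loops) for resistant over sensitive cells and 0.0809 (SD 0.0038) for shBORIS over shGFP. The ratios of all tags were 0.269 and 0.0237, and those of the tags outside the chromosome 2 segment 0.420 and −0.244. TMM factors from edgeR 4.0.16 gave 0.487 and −0.235. Tag ratios of classes, lengths, chromosomes and windows subtract the authors' scaling unless stated.

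The chromosome 2 segment is the run of 250 kb windows whose anchors carried at least 100000 tags in both tables. Tags outside it came to 414254 in resistant, 309653 in sensitive, 170619 in shBORIS and 202057 in shGFP cells. Windows of 10 Mb with at least 30 loops were compared with binomial redraws of their tags. Raised or lowered windows had a log2 ratio of at least 0.5 or at most −0.5, and a run holds at least 2 neighbouring windows. Within the segment, tag density is the tag count of a pair divided by the product of the anchor widths. Bootstrap intervals used 2000 draws over loops, windows, anchor pairs for the ratio of tag densities or, for distances around a circle, anchors. A pooled log2 ratio of single loops used a pseudocount of 0.5 tags wherever calls were made from it, and a binomial test at the authors' scaling, or at that of the tags outside the segment, was adjusted by Benjamini-Hochberg at 0.05.

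Loops were matched between tables as reciprocal best pairs whose anchors overlap by at least 1 bp at both ends. Alternatives used an overlap of 50% of the shorter anchor, or anchors within 5 kb. Relabelling of matched loops within each of the 6 classes was added after the result over all classes had been seen.

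The binomial test was checked on simulated data with 200 changed loops per table drawn from the real tag totals. For resistant against sensitive cells (43797 loops) it recovered 0% of 2-fold and 7% of 4-fold loops, and for shBORIS against shGFP (33640 loops) 0% of both, with 0 unchanged loops called in either. Among loops of at least 50 tags it recovered 84.0% and 88.5% of 4-fold changes. Matching returned 100% of 3000 loops shifted in position to themselves.

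Alternatives covered library totals, median-ratio factors, a factor per chromosome and a mean count of at least 10 per group column. Added after seeing the data were TMM, a factor from tags outside the segment, a factor per 10 Mb window, the pooled ratio, the binomial test with either factor, a loop FDR under 0.001, and pairs of at least 20 tags. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.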

Results

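Chromatin loops held by the cohesin subunit SMC1A were measured by HiChIP in Kelly cells, a neuroblastoma line that carries amplified copies of the MYCN region of chromosome 2. HiChIP joins stretches of chromatin that lie close together in the nucleus, pulls down the DNA bound by a chosen protein and sequences the joined ends as paired-end tags. The 12 libraries formed 4 groups of 3. Sensitive cells respond to the ALK inhibitor TAE684, and resistant cells were grown in 1 µM TAE684. Resistant cells carrying a short hairpin RNA against BORIS (shBORIS) were set against resistant cells carrying a hairpin against GFP (shGFP) as control. BORIS, also named CTCFL, is a paralog of the insulator protein CTCF that is normally made in the testis. The deposited tables hold 1 pooled tag count per group, so the values below have no replicate spread, and the level of BORIS was not measured by this assay.

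The table of resistant and sensitive cells listed 44945 loops with 2732585 tags in resistant and 2267821 tags in sensitive cells. The table of shBORIS and shGFP cells listed 34307 loops with 2747093 and 2702407 tags. The typical loop was shallow, with a median of 12 tags over both groups in the first table and 9 in the second. Intervals in the text are 95% intervals, Wilson for shares and exact Clopper-Pearson for ratios of tags. Those for ratios and shares of tags cover counting error only. Those for shares of loops treat loops as independent draws, although loops share anchors, and leave out the counting error within each call. Positions are those of the deposited tables.

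A single stretch of chromosome 2, from 15750001 to 17000000, carried most of the signal in every group. It held 84.8% of the tags in resistant cells (84.8 to 84.9%), 86.3% in sensitive cells (86.3 to 86.4%), 93.8% in shBORIS cells (93.8 to 93.8%) and 92.5% in shGFP cells (92.5 to 92.6%). Its 1148 loops in the first table had a median of 1622 tags, and 1038 of them joined 2 enhancers in the deposited annotation. Anchors of at least 10000 tags lay between 15833275 and 16841527 in the first table, where 47 such anchors formed 1079 of their 1081 possible pairs. The second table held 36 such anchors, between 15833275 and 16843481, which formed 626 of 630 pairs. The remaining anchors of the segment had at most 379 tags in the first table and 667 in the second. Within the segment the authors called 15 loops gained and 6 lost in resistant cells, and 1 gained and 4 lost under shBORIS.

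Tag density between these anchors fell with distance and rose again for the most distant pairs. In the first table the median was 30.7 tags per square kb of anchor for pairs up to 100 kb apart, 7.89 for pairs 400 to 600 kb apart and 12.9 for pairs over 800 kb apart. In the second table the same medians were 32.5, 9.07 and 18.4. The ratio of pairs over 800 kb to pairs of 400 to 600 kb was 1.63 in the first table (bootstrap interval 1.45 to 2.03, 42 and 222 pairs) and 2.03 in the second (1.41 to 2.47, 20 and 135 pairs). The draws were over pairs, which share anchors, so these intervals do not cover the spread between anchors. Density was not adjusted for the strength of single anchors.

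**Figure D1:**
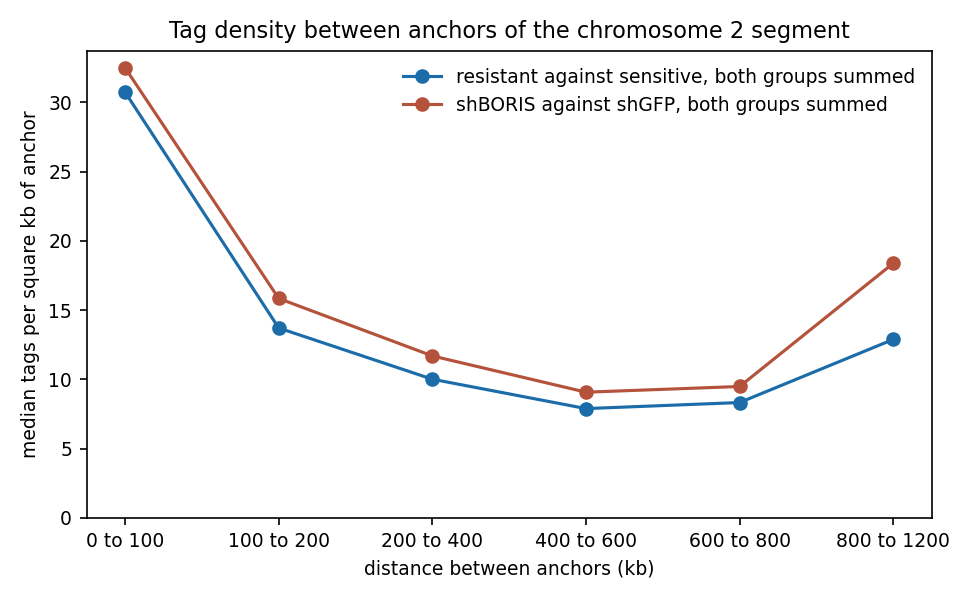
Median tags per square kb of anchor (vertical axis, both groups of a table summed) against the distance between anchors in kb (horizontal axis), for pairs of anchors with at least 10000 tags in the chromosome 2 segment. Each point is the median over the pairs of a distance class. The median falls to 7.89 and 9.07 at 400 to 600 kb and is 12.9 and 18.4 beyond 800 kb.

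The comparison of resistant with sensitive cells asked which loops differ between cells that tolerate TAE684 and cells that respond to it. Resistant cells were kept in TAE684 and the labels record none for sensitive cells, so resistance and drug exposure cannot be told apart. Loops called gained or lost in resistance are thus those of resistant cells under the drug against sensitive cells with no recorded drug. Enhancer-enhancer loops, chromosome 18 as a whole and stretches of chromosomes 12, 5 and 20 were higher in resistant cells. Loops between CTCF sites, stretches of chromosomes 16, 22, 3 and 8 and 1 window of chromosome 9 were lower. By the authors' 2-fold rule 9487 loops were gained (21.1%, 20.7 to 21.5%) and 6998 were lost (15.6%, 15.2 to 15.9%). Lost loops made up 42.5% of the calls (41.7 to 43.2%), and 52.3% when the scaling was changed to a TMM factor.

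Outside the segment, 26.3% of the 10563 enhancer-enhancer loops were gained and 11.7% lost, and their median log2 fold change of 0.35 lay 0.22 above that of the other classes. Of the 6141 loops between CTCF sites, 17.4% were gained and 22.0% lost, with a median 0.24 below the other classes (difference −0.24). Loops from a CTCF site to a promoter lay below the other classes too (difference −0.15), as did promoter-promoter loops (−0.09). Loops from a CTCF site to an enhancer (0.06) and enhancer-promoter loops (0.03) lay slightly above. Each of these 6 class medians fell outside the central 95% of 10000 random lists matched on tag total. The enhancer-enhancer median lay above all of the random lists, whose range was 0.14 to 0.18, and the CTCF site median of −0.03 lay below all of theirs, at 0.18 to 0.25. Among loops with a mean count of at least 10 the differences shrank to 0.14 for enhancer-enhancer and −0.15 for CTCF site loops. After each 10 Mb window was centred on its own tag ratio, enhancer-enhancer loops stayed 0.16 above and CTCF site loops at −0.19 to the other classes. Centring left promoter-promoter loops at −0.04 and loops from a CTCF site to an enhancer at 0.05, both within their random ranges.

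**Figure D2:**
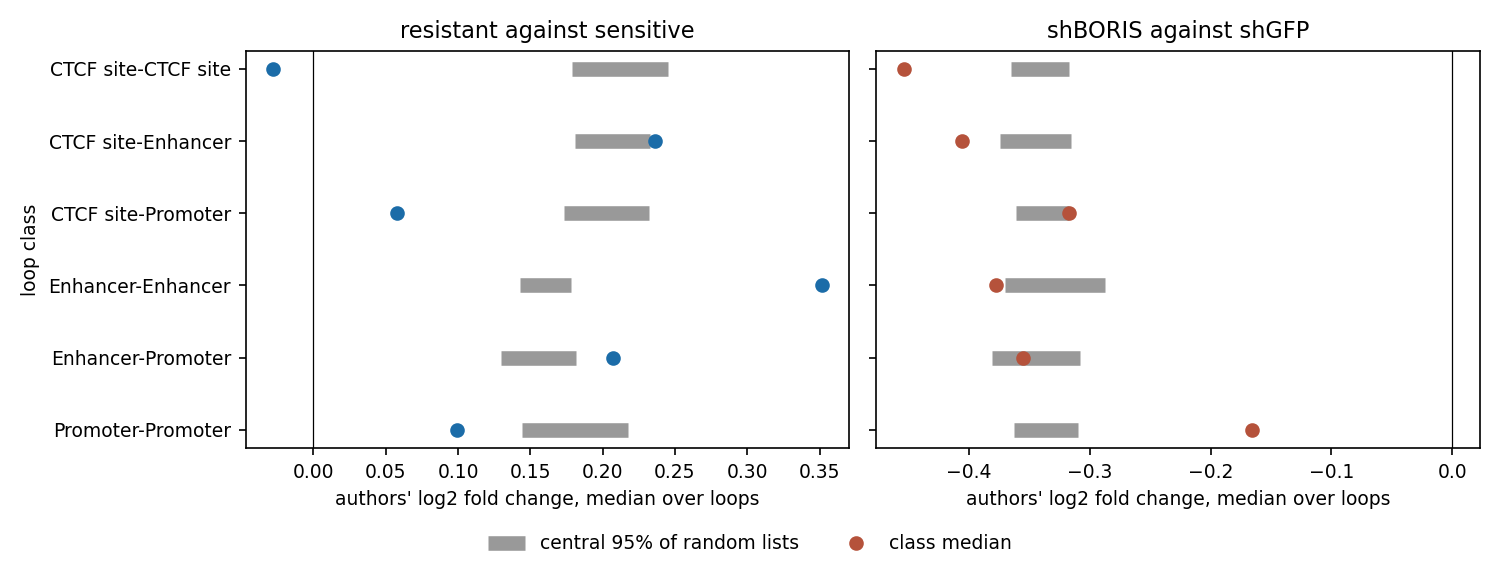
Median of the authors' log2 fold change over loops outside the chromosome 2 segment (horizontal axis) for each of the 6 loop classes (vertical axis), with resistant against sensitive cells on the left and shBORIS against shGFP on the right, on separate scales. Points are class medians and grey bars span the central 95% of 10000 random lists matched on tag total. Enhancer-enhancer loops stand highest in resistant cells at 0.35 and promoter-promoter loops highest under shBORIS at −0.17.

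Loops on chromosome 18 had a tag ratio of 0.73 on the log2 scale (0.63 to 0.83) in resistant over sensitive cells, and 42.7% of them were gained. Chromosome 12 had a ratio of 0.44 (0.41 to 0.46), chromosome 20 of 0.37 (0.34 to 0.40) and chromosome 2 outside the segment of 0.28 (0.26 to 0.31). Chromosome 16 had a ratio of −0.66 (−0.74 to −0.58) with 43.4% of loops lost, chromosome 22 of −0.51 (−0.55 to −0.47) and chromosome 8 of −0.27 (−0.34 to −0.21). The longest run of raised 10 Mb windows covered chromosome 12 from 60 to 140 Mb, where all 8 windows lay between 0.78 and 1.17 and 879 of 1891 loops were gained against 81 lost. Chromosome 5 from 0 to 20 Mb had 143 gained and 19 lost of 320 loops, and chromosome 20 from 30 to 50 Mb had 378 gained and 48 lost of 1014. Lowered runs lay on chromosome 16 from 50 to 70 Mb (5 gained, 82 lost), chromosome 3 from 40 to 60 Mb (5 gained, 89 lost), chromosome 22 from 30 to 60 Mb (59 gained, 257 lost) and chromosome 8 from 130 to 150 Mb (17 gained, 87 lost). The lowest single window was chromosome 9 from 30 to 40 Mb at −1.35 (−1.57 to −1.14), while chromosome 9 as a whole lay at −0.01 (−0.05 to 0.02). Over the 217 windows the SD was 0.402, against at most 0.0916 in the central 95% of redraws with counting error alone.

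**Figure D3:**
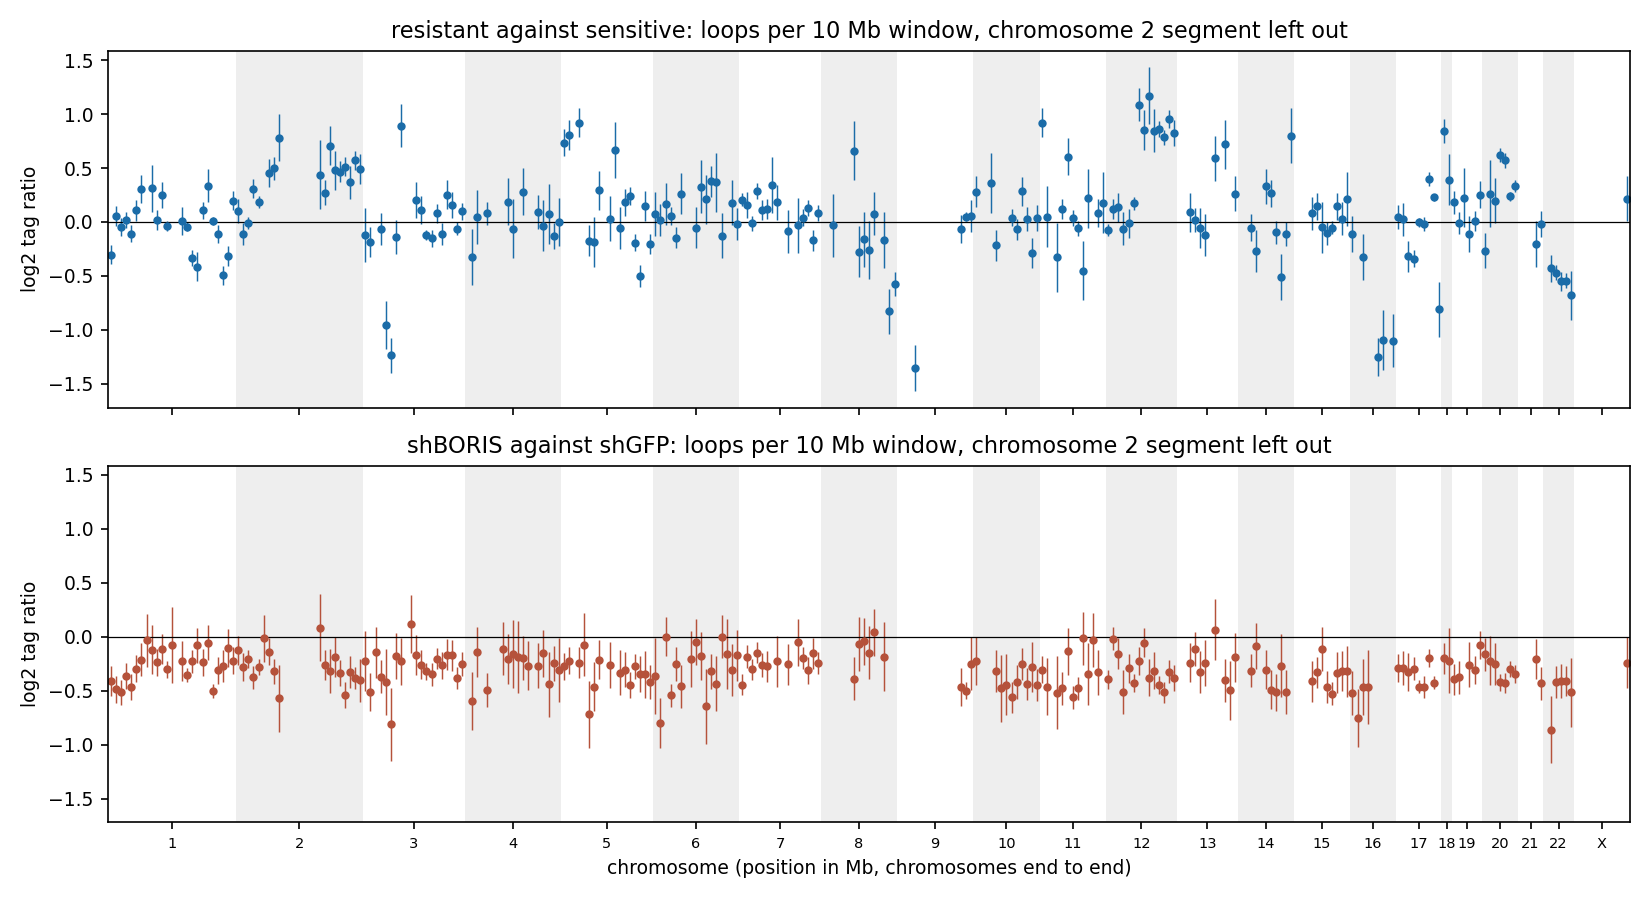
Log2 tag ratio of loops per 10 Mb window (vertical axis, authors' scaling) along the chromosomes (horizontal axis, Mb), with resistant over sensitive cells above and shBORIS over shGFP below. Points are windows of at least 30 loops outside the chromosome 2 segment, with exact 95% intervals. Chromosome 12 from 60 to 140 Mb lies between 0.78 and 1.17 in the upper panel, and the SD over windows is 0.402 above and 0.164 below.

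The 10 gained loops of largest fold change were spread over 8 chromosomes, and 7 of them joined 2 enhancers. On chromosome 13, loop119023 joined 91806270 to 91812697 with 91867271 to 91872270. It had 27 tags in resistant and 0 in sensitive cells, a pooled log2 ratio with a lower limit of 2.44, and a log2 fold change of 3.74 in the authors' deposited table. The enhancer-enhancer loop109074 on chromosome 12 (55385027 to 55390026 with 55449893 to 55455689) had 36 tags against 2, a pooled log2 ratio of 3.83 (1.88 to 6.93). The enhancer-promoter loop23256 on chromosome 1 (244210025 to 244230118 with 244357333 to 244362332) had 31 tags against 1, a pooled log2 ratio of 4.62 (2.03 to 9.97).

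Among the 10 lost loops of largest fold change, 4 joined CTCF sites and 4 joined enhancers. The deepest, loop12469, joined 162850966 to 162860738 with 162884989 to 162891944 on chromosome 1. It had 11 tags in resistant and 117 in sensitive cells, a pooled log2 ratio of −3.75 (−4.79 to −2.86). Its first anchor was shared with loop12495, which reached 310.3 kb to 163163530 to 163168697 and had 2 tags against 30 (−4.24, −7.35 to −2.26). Loop22184 on chromosome 1 (234678211 to 234683210 with 234734350 to 234749459), an enhancer-promoter loop, had 5 tags against 37 (−3.22, −4.93 to −1.87). On chromosome 3, loop42591 (52175616 to 52184423 with 52185230 to 52191392) had 3 tags against 22 (−3.21, −5.59 to −1.48).

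Gained loops were shorter than lost loops, with medians of 72.4 and 76.6 kb. The difference of −4.14 kb lay below the −0.72 to 5.88 kb that relabelling within classes of equal depth gave. It was −1.58 kb when the factor came from tags outside the segment, −6.40 kb with a factor per 10 Mb window, and −15.4 kb among loops with a mean count of at least 10, with no relabelling of their own. By tag ratio, loops over 320 kb were not lower in resistant cells, at 0.12 (0.09 to 0.15) against 0.08 (0.06 to 0.09) for loops up to 20 kb. The ratio of loops of 160 to 320 kb was 0.05. Of loops over 320 kb, 28.3% were gained and 19.3% lost, against 10.6% and 6.54% of loops up to 20 kb. The long loops had a median of 10 tags and the short ones of 31. Shallow loops pass a 2-fold rule more often by counting error, so these shares do not show that long loops changed more. Few single loops passed a test of their own. A two-sided binomial test of the pooled tags outside the segment, with Benjamini-Hochberg adjustment at 0.05, left 57 loops higher and 54 lower by at least 2-fold on the authors' scaling, and 39 higher and 68 lower with a factor from the tags outside the segment. Which direction had more loops thus depended on the scaling, and the test compares these pools, not the conditions. Redraws that gave every loop outside the segment the same ratio, their common one of 0.08 on the authors' scale, held 8437 gained and 4291 lost loops by the pooled ratio, against 10067 and 6359 observed. These expected counts carry that common shift besides counting error, and loops below the lowest count of the table were drawn again. What part of their excess of gained loops comes from the shift, from the lowest count or from the depth of the pools was not tested. By the authors' rule, loops under 10 tags held 5558 gained and 3646 lost, with a median log2 fold change of 0.68. Loops of at least 20 tags held 1054 gained and 720 lost, with a median of 0.0065.

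The comparison of shBORIS with shGFP asked how loops of resistant cells differ when BORIS is targeted. Promoter-promoter loops kept more of their tags than other loops under shBORIS, and loops between CTCF sites and loops over 80 kb long kept fewer. By the authors' 2-fold rule 3807 loops were gained (11.1%, 10.8 to 11.4%) and 9903 were lost (28.9%, 28.4 to 29.3%), so lost loops made up 72.2% of the calls (71.5 to 73.0%). That share was 49.7% with scaling on the tags outside the chromosome 2 segment, 50.5% with a TMM factor, 49.99% with median-ratio factors, 50.7% with a factor per chromosome and 48.7% with a factor per 10 Mb window. It was 65.1% with library totals, 65.6% by pooled ratio and 88.9% among loops with a mean count of at least 10. The pooled ratio and the mean count keep the authors' factor, so they do not test the scaling. A scaling on the tags outside the segment shifted all loops by 0.32 on the log2 scale, so the values that follow are read against each other.

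Promoter-promoter loops had a median log2 fold change of −0.17, which was 0.21 above that of the other classes, with 24.7% of 5516 loops lost and 13.4% gained. Their median lay above all 10000 random lists matched on tag total, and also above all lists matched on tag total and length. Loops between CTCF sites had a median of −0.45, a difference of −0.14 to the other classes, with 32.7% of 6765 loops lost and 9.43% gained. They lay below all random lists in both kinds of matching. Loops from a CTCF site to an enhancer lay at −0.08 to the other classes, outside the lists matched on tag total but inside those matched on length too. Loops from a CTCF site to a promoter lay 0.02 above the other classes, and enhancer-promoter loops at −0.03 lay within the random range, but stood at −0.15 among loops with a mean count of at least 10, below the −0.10 of CTCF site loops there. Enhancer-enhancer loops lay at −0.05 to the other classes. Their median of −0.378 was just below the random lower ends of −0.370 and, with length matched too, −0.361. After centring on 10 Mb windows they lay within the random range, and their difference turned to 0.02 among loops with a mean count of at least 10.

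Loops up to 20 kb long had a tag ratio of −0.20 (−0.22 to −0.18) in shBORIS over shGFP cells on the authors' scale, and loops of 20 to 40 kb of −0.22 (−0.24 to −0.19). The ratio was −0.33 at 40 to 80 kb, −0.41 (−0.43 to −0.39) at 80 to 160 kb and −0.40 (−0.42 to −0.37) over 320 kb. Gained loops had a median length of 110 kb and lost loops of 120 kb, a difference of −10.4 kb against a random range of 0.01 to 12.9 kb, and of −1.64 kb when calls came from the pooled ratio. It was −31.8 kb among loops with a mean count of at least 10, −17.6 kb with the factor from tags outside the segment and −22.0 kb with a factor per 10 Mb window, with no relabelling of their own.

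**Figure D4:**
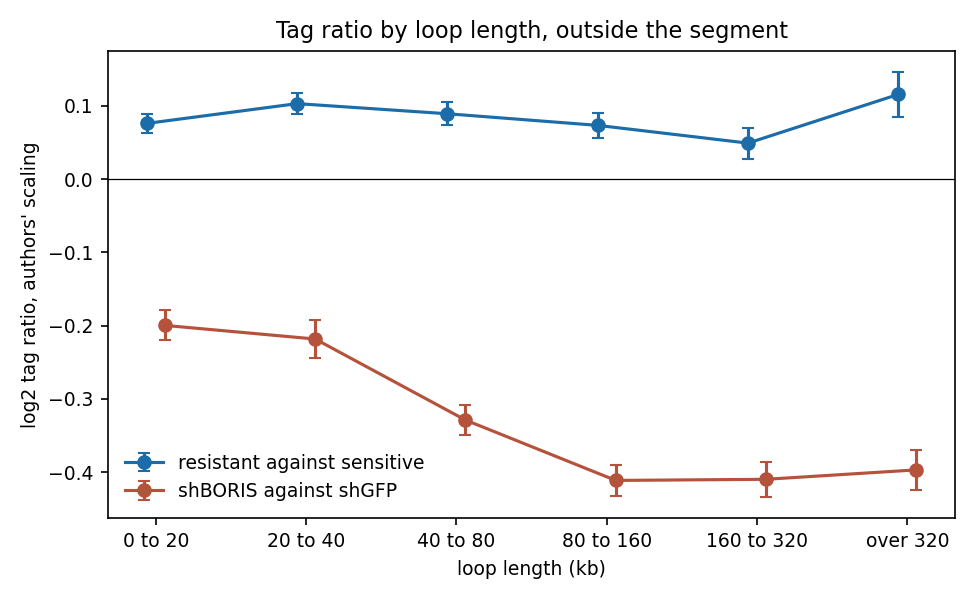
Log2 tag ratio on the authors' scaling (vertical axis) by loop length in kb (horizontal axis) for loops outside the chromosome 2 segment. Points are pooled ratios with exact 95% intervals for resistant over sensitive cells and for shBORIS over shGFP. Under shBORIS the ratio falls from −0.20 for loops up to 20 kb to −0.40 over 320 kb, and scaling on the tags outside the segment would move all shBORIS points up by 0.32, which puts loops up to 40 kb above 0.

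Chromosomes moved more alike than in the first comparison. On the authors' scale the tag ratio ran from −0.16 (−0.25 to −0.07) on chromosome 8 to −0.58 (−0.70 to −0.46) on chromosome 16, and the 220 windows had an SD of 0.164 against at most 0.107 in such redraws. Of the runs raised in resistant cells, relative to all loops outside the segment, chromosome 12 from 60 to 140 Mb lay at −0.03 (−0.08 to 0.01) under shBORIS, chromosome 5 from 0 to 20 Mb at 0.08 (−0.01 to 0.17) and chromosome 20 from 30 to 50 Mb at −0.10 (−0.16 to −0.04). Of the lowered runs, chromosome 8 from 130 to 150 Mb lay at −0.76 (−1.25 to −0.28), chromosome 16 from 50 to 70 Mb at −0.57 (−1.06 to −0.10), chromosome 3 from 40 to 60 Mb at −0.27 (−0.50 to −0.05) and chromosome 22 from 30 to 60 Mb at −0.10 (−0.19 to 0.00). The runs of chromosomes 8 and 16 held only 18 and 19 loops in this table.

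The lost loop of largest fold change under shBORIS was the promoter-promoter loop182469 on chromosome 5, between 312575 to 324676 and 507686 to 529987. It had 0 tags in shBORIS and 16 in shGFP cells, a pooled log2 ratio with an upper limit of −2.03, and a log2 fold change of −3.60 in the authors' deposited table. On chromosome 3, loop140088 joined 155865798 to 155875728 with 156098621 to 156103620, both CTCF sites, and had 0 tags against 12. The 10 lost loops of largest fold change included 3 on chromosome 12, all between 5533297 and 6940321, with 0 tags in shBORIS cells and 10 to 12 in shGFP cells. Of the 10 gained loops, the CTCF site to enhancer loop16871 on chromosome 1 (99447660 to 99479147 with 100133498 to 100153078) had the largest fold change, with 12 tags against 0 and a lower limit of 1.39 for the pooled log2 ratio. The binomial test of the pooled tags outside the segment left 0 loops higher and 2 lower on the authors' scaling, and 0 and 1 with the factor from outside the segment. Redraws that gave every loop outside the segment the same ratio, their common one of −0.32 on the authors' scale, held 3945 gained and 8246 lost loops by the pooled ratio, against 4788 and 9144 observed. These expected counts too carry that common shift besides counting error, so their excess of lost loops is not one of counting error alone.

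Setting the tables side by side asked whether loops gained in resistance were those lost under shBORIS. Over all classes together, they were lost at a rate within the range of other loops of the same depth and length. Outside the segment 10636 loops matched between the tables with both anchors overlapping, among them 22.1% of the gained, 19.99% of the lost and 26.2% of the uncalled loops of the first table. Of the 2089 matched loops gained in resistance, 637 were lost under shBORIS (30.5%, 28.6 to 32.5%). The share was 31.2% (28.8 to 33.7%) for loops lost in resistance and 27.8% (26.8 to 28.9%) for uncalled loops. Gained loops exceeded all other matched loops by 2.12 percentage points (bootstrap interval 0.10 to 4.23), within the −0.26 to 4.03 points that relabelling gave for loops of equal depth and length. The difference was 0.53 points with a factor from tags outside the segment in both tables and 0.82 by pooled ratio. It was 2.81 points for pairs with at least 20 tags in both tables, 2.16 with 50% overlap and 2.23 with anchors within 5 kb. The 6 classes, as the first table names them, were then examined one by one. Enhancer-promoter loops gained in resistance were lost in 33.8% of 396 cases against 26.6% of 1676 others, a difference of 7.23 points at the upper end of the relabelled range of −2.45 to 7.23. For loops from a CTCF site to an enhancer the difference was −3.60, below the relabelled −2.94 to 6.98, and the other 4 classes lay inside their ranges. Only 62.2% of the matched enhancer-promoter loops and 53.6% of those from a CTCF site to an enhancer had the same class in the second table, so these differences hold for the first table's naming only. For independent lists 601.4 loops would be gained and then lost. Across matched loops, which are not independent replicates, Pearson's r of the fold changes was −0.0068 and Spearman's rho −0.0037, with r within the relabelled range of −0.02 to 0.02. For pairs with at least 20 tags in both tables r was −0.0035. By pooled ratio, the redraws above held 8437 gained loops against 10067 observed in the first table, and 8246 lost against 9144 in the second. Such counting error weakens any link between the tables, so these values do not show that the changes are unrelated.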

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

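The TMM factor, the factor from tags outside the segment, the factor per 10 Mb window, the pooled ratio, the binomial test with either factor and the stricter loop FDR were chosen after the result was seen. No paired analysis was possible because the deposited columns pool the replicates of a group and carry no replicate number. For the same reason the planned edgeR, DESeq2 and limma-voom tests, the adjusted p-value thresholds, the replicate block and leaving out each replicate were not run, nor were the gene list alternatives. The main values used no filter on low counts, and the 2-fold rule is already the authors' call. The 40 named loops were chosen for their large fold changes, so that they stayed past 2-fold under every scaling says nothing of their stability. Of them 12 had a mean count of at least 10 and 16 passed the binomial test.

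In resistant against sensitive cells, a mean count of at least 10 left 1054 gained and 720 lost loops by removing shallow loops. The binomial test with the 2-fold rule, which asks for an adjusted p and takes only loops outside the segment, left 57 and 54, and 39 and 68 with the factor from tags outside the segment. The lost share of 42.5% became 38.5% with library totals, 51.1% with median-ratio factors, 45.8% with a factor per chromosome, 52.3% with TMM, 47.2% with the factor from tags outside the segment, 49.1% per window, 38.7% by pooled ratio, 40.6% at a mean count of at least 10, 48.6% by the binomial test and 63.6% by that test with the factor outside the segment. At that mean count the difference of CTCF site loops became −0.15, that of enhancer-enhancer loops 0.14 and the length difference −15.4 kb. With a factor per window these classes stood at −0.19 and 0.16.

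In shBORIS against shGFP, 3807 gained loops became 6768 with median-ratio factors, 6587 per chromosome, 6640 with TMM, 6835 with the factor from tags outside the segment and 6631 per window, where 9903 lost loops became 6290. A mean count of at least 10 left 72 gained and 578 lost, the binomial test 0 and 2, and that test with the factor outside the segment 0 and 1. The lost share of 72.2% became 65.1% with library totals, 49.99% with median-ratio factors, 50.7% per chromosome, 50.5% with TMM, 49.7% outside the segment, 48.7% per window, 65.6% by pooled ratio, 88.9% at a mean count of at least 10 and 100% by the binomial test with either factor. CTCF site loops stood at −0.10 at that mean count and −0.11 by pooled ratio, promoter-promoter loops at 0.30 by pooled ratio, and enhancer-enhancer loops turned from −0.0538 to 0.0179 at that mean count. The length difference was −31.8 kb at that mean count, −17.6 kb with the factor outside the segment, −22.0 kb per window and −1.64 kb by pooled ratio. Except where the mean count removed shallow loops or a factor shifts all loops, the cause was not tested. Depth limits single loops, since a median of 12 or 9 tags cannot show a 2-fold change.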

Other observations

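The tests of counting error, of scaling, of a lower yield of long loops and of copies joined end to end were chosen after the result was seen, as were the anchor regions named here and the relabelling within single loop classes. The tests of a regional bias, of copy number and of the matched loops were chosen before.

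Summing tags over all loops of an anchor gave more depth than single loops. Of 2660 anchor regions with at least 50 tags in both tables, 362 were higher and 226 lower in resistant cells by a binomial test of the pooled tags (Benjamini-Hochberg at 0.05, relative to all tags outside the segment), and 3 were higher and 16 lower under shBORIS. The region of chromosome 13 from 91867271 to 91872330 had 122 tags in resistant and 14 in sensitive cells, a log2 ratio of 2.70 (1.90 to 3.62), and the region of chromosome 20 from 38193624 to 38204733 had 80 against 10. On chromosome 1 the region from 162883318 to 162892824 had 96 tags in resistant and 296 in sensitive cells (−2.04, −2.39 to −1.71).

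The test called 4 regions both higher in resistant cells and lower under shBORIS, against 2.18 for independent lists. It called 2 lower in both, against 1.36, 0 lower and then higher, against 0.25, and 1 higher in both, and Pearson's r of the log2 ratios across regions was −0.00500. The 4 regions were chromosome 1 from 39070805 to 39084165 (111 against 48 tags, then 11 against 50), chromosome 2 from 233178192 to 233194570 (65 against 25, then 24 against 74), chromosome 1 from 212647179 to 212653768 (62 against 23, then 27 against 71) and chromosome 7 from 2551763 to 2558760 (248 against 136, then 31 against 88). Among those lower in both, the region of chromosome 7 from 25426620 to 25432643 had 26 against 84 tags in resistant and sensitive cells and 13 against 48 in shBORIS and shGFP cells.

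Whole stretches of chromosomes moved together between resistant and sensitive cells. The 26 windows raised by at least 0.5 held 22.1% of gained loops and 11.2% of all loops outside the segment. These windows were picked by the tag ratio of their own loops, so this excess follows from the choice and is no separate support. Counting error does not account for the spread between windows, since the SD over windows was 0.402 against 0.0916 from redraws. A copy number difference between the lines is a candidate explanation: loops between CTCF sites and loops of enhancers and promoters shifted together across windows (r = 0.639, bootstrap interval 0.523 to 0.734). In shBORIS against shGFP, both resistant, r was 0.317 (0.166 to 0.444). Windows there varied little beyond counting error (SD 0.164 against 0.107 from redraws), which lowers r, so this contrast is no separate support. Any regional shift would move both loop kinds, so neither r sets copy number apart. A regional bias that also acts between libraries of 1 line stays open, because window ratios of both comparisons had r = 0.152 with an interval of −0.00711 to 0.304. Single runs went both ways. Relative to loops outside the segment, the lowered runs of chromosomes 8, 16 and 3 were also lower under shBORIS (−0.76, −0.57 and −0.27, on 18, 19 and 69 loops) and that of chromosome 22 lay at −0.10 (−0.19 to 0.00), while the raised runs of chromosomes 12, 5 and 20 lay at −0.03, 0.08 and −0.10 on 1701, 335 and 851 loops, the last lower and not higher (−0.16 to −0.04). Copy number was not measured here, and a change of chromatin that comes with resistance or with exposure to the drug was not tested.

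Whether the excess of lost loops under shBORIS comes from the scaling stays open. How the authors set their factor is not known, and at 0.0809 it lies above the log2 ratio of all tags (0.0237), of tags inside the segment (0.0433) and of tags outside it (−0.244). The lost share of 72.2% was 65.1% with library totals, which missed the bound set for scaling on totals as the cause. The segment held 93.8% of the tags in shBORIS and 92.5% in shGFP cells, so library totals rest on it too. The missed bound thus cannot decide. The lost share was 49.7% when the factor came from tags outside the segment, but that factor centres these loops by construction. Fewer loops outside the segment and more tags within it therefore cannot be told apart. A lower yield of long loops is not the whole cause, since loops up to 20 kb outside the segment also lay below the segment, by −0.162 on the log2 scale (−0.183 to −0.141). An effect of BORIS on loops stays open and was not tested apart from these.

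Loops gained in resistance were lost under shBORIS 2.12 percentage points more often than other matched loops. Loops of equal depth and length relabelled at random gave −0.26 to 4.03 points, so depth and length could account for the difference over all classes. Centring both tables on 10 Mb windows left 1.78 points, a factor from tags outside the segment 0.53 and the pooled ratio 0.82. The difference was 2.81 points for pairs with at least 20 tags in both tables, 2.16 with 50% overlap and 2.23 with anchors within 5 kb. With a difference inside the random range, a part from copy number cannot be told apart.

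A hypothesis for the rise in tag density between distant anchors of the chromosome 2 segment is that amplified copies are joined end to end, in tandem or as circles, which would bring the ends of neighbouring copies close. Over all anchor pairs, distance around a circle of the length of the segment between its outer anchors tracked tag density more closely than linear distance (difference in Spearman's rho −0.0841 in the first table and −0.0609 in the second), but this restates the rise and is no separate support. The test therefore left out the pairs over 800 kb that show the rise, and resampled anchors because pairs share them. The difference was then −0.0130 in the first table (bootstrap interval −0.0706 to 0.0332, 1037 pairs) and 0.0118 in the second (−0.0575 to 0.0747, 606 pairs). The pairs up to 800 kb thus do not decide, no junction reads were analysed here, and the hypothesis stays open.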
